A study of Mus musculus with 16 samples.

How the data were processed

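Microglia from the cortex of C57BL/6J mice were isolated by fluorescence-activated cell sorting after 1 week on chow with PLX3397 or control chow, per the labels' protocols. Per the labels' protocols, cDNA was made from 500 pg of total RNA with a SMARTer kit for low input, and 150 pg of it went into Nextera XT libraries. The 16 libraries form 4 groups of 4, all used, and each column of the table was mapped to a sample by its label. The sources used here do not give the gate of the sort or the ages in days. They also do not say whether the 4 samples of a group were separate animals. The p-values of genes and of library measures therefore measure the spread between these samples.

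The deposited table holds a signal for 53850 genes in each library: per its name and values, read counts per gene divided by a factor that differs by library and slightly by gene. The submitters' processing notes name bcl2fastq 2.19.1, STAR 2.7.9a, Subread, featureCounts 2.0.1, Salmon 1.5.2 and the build GRCm39, with no role or order; the formula of the normalisation and the annotation release are not given. Low values of a library fell near multiples of a step of 0.517 to 1.88, which puts its reads at about 22200000 to 78500000. Each male control library had more estimated reads than any library of males on PLX3397 or of female controls. By two-sided exact permutation p was 0.0286 for each (adjusted p = 0.0449 between males and 0.314 between controls). Genes at 0 in males on PLX3397 or in female controls were thus compared with male controls at unequal depth. In males, genes with a value of at least 10 numbered 17939 to 18967 on PLX3397 and 17637 to 17928 on control chow (adjusted p = 0.0449, same test). Whole reads were not recovered gene by gene, so count models were not used. Intervals from counting error were therefore not computed, and precision is given as SE, whose median over genes was 0.292 for a comparison of groups and 0.413 for the difference between responses. In all, 20817 genes were at 0 in every library. Symbols came from an Ensembl-based table of build GRCm38 for 51029 of the 53850 identifiers and for 19407 of those tested, and no coordinates are printed.

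Genes with a value of at least 10 in at least 4 libraries were tested (19594) on log2(value + 1), with limma 3.58.1 in R 4.3.3 (trend on intensity, 1 mean per group over all 16 libraries, two-sided tests, Benjamini-Hochberg adjusted p under 0.05). The 5 comparisons were PLX3397 against control chow in males and in females, the difference between these responses (females minus males), and females minus males on each chow. A total of 40 gene lists were fixed, and the 35 with at least 5 measured members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with fry, and with exact permutation of the mean per library. At the preset correlation, camera compares a list's genes with the other genes. Its p-value rests on the spread between genes and on that assumed correlation, and not on the spread between libraries alone. Library measures were compared by two-sided exact permutation tests, adjusted over the measures. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

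Genes were named by a rule. It always names Csf1r, Csf1, Il34, P2ry12, Tmem119, Cx3cr1, Trem2, Apoe, Xist, Ddx3y, Kdm5d, Uty and Eif2s3y. For each comparison it takes the 8 largest rises and 8 largest falls among called genes with groups that do not overlap and a higher group mean of at least 50, leaving out gene models without a proper name, and up to 4 members of each list with the smallest p. The text names part of what the rule gave. Meg3, S100b, Rpl36, Gfap, Canx, Psmd1 and Ly6c2, and Cd44 in males, were left out because their calls ended under alternatives. Il6, Nlrp3, Nfkb1 and Il1a are named in addition, because they fell where their list rose. The comparisons, tests, gene lists, naming rule and first set of alternatives were chosen before the data were examined. That set held pseudocounts of 0.5 and 5, other filters, upper-quartile scaling, quantile normalisation, a fit to the groups compared alone, array weights, a replicate block and each library left out. Added after seeing the data were voom weights on values divided by the step, equal library totals, both together, removal of the trend over GC content and transcript length, the mean per library of each list, and leaving out 2 libraries that stood apart, male control replicate 4 for its Xist and male PLX3397 replicate 3 for its S100a8.

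The procedure was tested on simulated data of 18781 genes with the same groups, with changes placed in males on PLX3397. In the male comparison it called 7 of 64 genes changed 1.5-fold, 30 of 63 changed 2-fold and 39 of 62 changed 4-fold, and 10 unchanged genes (0.0539%). In the difference between responses it called 4.69%, 19.0% and 50.0% of these and 4 unchanged genes. A raised list was called in males (camera adjusted p = 1.5e-17) and 0 of 30 unchanged lists were. Far fewer genes were changed in the simulation than the 2289 called in males. Its cut-off on the unadjusted p may therefore be stricter, and recovery in males understated. The simulated genes varied independently and the unchanged lists were random, so false calls of lists with correlated genes were not tested. In males the estimated correlation was 0.484 for the homeostatic list and 0.707 for mitochondrially encoded genes, against the preset 0.01.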

Results

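RNA was sequenced from cortical microglia of young C57BL/6J mice that ate chow with PLX3397, an inhibitor of the CSF1 receptor, or control chow for 1 week. Microglia need signalling through this receptor to survive, and the series asks how the response of those that remained differed between males and females. The 16 libraries formed 4 groups of 4: males and females on either chow. The normalised read counts of a library summed to between 32600000 and 44200000, and 19594 genes passed the filter on low values. Means are normalised read counts ± SD with n = 4, and changes are log2 fold changes ± SE on the log2(value + 1) scale. Adjusted p-values of genes come from limma with Benjamini-Hochberg adjustment, and those of gene lists from camera in limma over 35 lists. On the first principal component, which held 16.8% of the variance, the groups lay at 44.4 ± 7.06 for male controls, 60.2 ± 16.4 for female controls, -69.1 ± 6.06 for males on PLX3397 and -35.5 ± 11.2 for females on PLX3397.

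The comparison of males on either chow asks what receptor inhibition did to surviving male microglia. Homeostatic microglial transcripts fell on PLX3397. P2ry12, a purinergic receptor of resting microglia, went from 247500 ± 12800 to 58080 ± 10600, a change of -2.11 ± 0.116 (adjusted p = 3.87e-08). Tmem119 changed by -2.38 ± 0.223 (adjusted p = 3.18e-06), the fructose transporter gene Slc2a5 by -3.84 ± 0.213 (adjusted p = 3.87e-08), and the fractalkine receptor gene Cx3cr1 by -1.02 ± 0.104 (adjusted p = 6.93e-06). Csf1r, which encodes the receptor, fell by 0.56 ± 0.0933 (adjusted p = 0.000729). The gene of its ligand Csf1 rose from 763.1 ± 77.0 to 3812 ± 1290, by 2.26 ± 0.277 (adjusted p = 4.43e-05). Il34, which encodes the other ligand, was listed at 0 in all 16 libraries. Dusp6 and Etv5, targets of ERK signalling in many cells, and the cyclin D1 gene Ccnd1 fell by 2.11 ± 0.151, 2.39 ± 0.222 and 3.36 ± 0.387. Their list, the CSF1R axis and related kinases, did not pass as a whole (median -0.11, camera adjusted p = 0.133). Of its 25 genes 5 were higher, 8 lower and 12 not past the test. Its adjusted p was 0.476 with an estimated correlation and 0.00325 by fry.

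Of the 31 genes on the homeostatic microglia list, 28 fell in males and 3 did not pass the test, with a median change of -1.06 and 28 lower when adjusted over the list alone (camera adjusted p = 4.25e-30; adjusted p = 0.0619 with an estimated correlation). P2ry13 and Selplg changed by -2.24 ± 0.162 and -1.84 ± 0.155. The disease-associated microglia list moved the other way, with 24 of 29 genes higher, 5 not past the test and 26 higher when adjusted over the list alone (median 1.74, camera adjusted p = 7.27e-28; adjusted p = 0.0619 with an estimated correlation). Its members Lgals3 and Lilrb4a rose by 6.03 ± 0.482 and 5.89 ± 0.435, and the lectin receptor gene Clec7a by 3.68 ± 0.236. Cst7 rose by 3.44 ± 0.25, the fatty acid binding protein gene Fabp5 by 3.72 ± 0.476, Lyz2 by 2.45 ± 0.143, Axl by 2.21 ± 0.2, Lpl by 2.16 ± 0.295 and Apoe by 2.01 ± 0.276. Trem2, on the same list, changed by 0.12 ± 0.119 and did not pass (adjusted p = 0.618).

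Other immune lists were higher in males on PLX3397. On the type I interferon response list, 17 of 36 genes rose, none fell and 19 did not pass, with 24 higher when adjusted over the list alone (median 1.16, camera adjusted p = 4.36e-12; adjusted p = 0.1 with an estimated correlation). Ifi204 and Ifitm3 rose by 1.87 ± 0.268 and 1.78 ± 0.265. Among 26 inflammatory cytokine and NF-kB genes, 12 rose, 4 fell and 10 did not pass, and over the list alone 14 rose and 5 fell (median 0.55, camera adjusted p = 0.000137; adjusted p = 0.257 with an estimated correlation). The chemokine genes Ccl4, Ccl3 and Cxcl16 rose by 3.14 ± 0.276, 2.75 ± 0.271 and 1.97 ± 0.19. The 4 members that fell were Il6 (-1.77), Nlrp3 (-1.13), Nfkb1 (-0.99) and Il1a (-0.78), with limma adjusted p = 0.00518, 0.00249, 1.17e-05 and 0.000493. The class I genes H2-D1 and H2-K1 rose by 1.31 ± 0.136 and 1.10 ± 0.122, but the antigen presentation list did not pass, with 8 of 24 genes higher, 4 lower and 12 not past the test (8 higher and 5 lower when adjusted over the list alone; camera adjusted p = 0.0841). That list passed without male PLX3397 replicate 2 (adjusted p = 0.0302) or replicate 3 (adjusted p = 0.0387), with equal library totals (adjusted p = 0.0411) and with quantile normalisation (adjusted p = 0.00116). Large rises outside these lists were those of Gadd45b, a stress response gene (4.61 ± 0.548), Rab7b (6.60 ± 1.08), Plxnc1 (6.00 ± 1.18) and Mmp9, a neutrophil marker (6.69 ± 1.54). Mmp9 lost its call when male PLX3397 replicate 3 and male control replicate 4 were left out together (adjusted p = 0.0824). Pira2 and Pilrb1 were listed at 0 in all 4 male control libraries and at 47.1 to 112.7 and 45.5 to 105.4 on PLX3397.

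Among organelle and translation genes, the lysosome list had 18 of 52 genes higher, 4 lower and 30 not past the test, and 23 higher and 6 lower when adjusted over the list alone (median 0.29, camera adjusted p = 2.82e-05; adjusted p = 0.482 with an estimated correlation). Ctsb, a lysosomal protease gene, rose by 1.45 ± 0.129 and Cd63 by 1.74 ± 0.141. Of 40 proteasome genes, 9 fell and 31 did not pass, with 14 lower when adjusted over the list alone (median -0.29, camera adjusted p = 1.35e-06; adjusted p = 0.342 with an estimated correlation). Psmc2, Adrm1 and Psmc1 fell by 0.63 ± 0.134, 0.57 ± 0.111 and 0.47 ± 0.0995. Of the 13 mitochondrially encoded respiratory chain genes, 12 rose and 1 did not pass, and all 13 were higher when adjusted over the list alone (median 0.84, camera adjusted p = 1.85e-14; adjusted p = 0.125 with an estimated correlation). Here mt-Nd4 rose by 1.01 ± 0.113 and mt-Co1 by 0.84 ± 0.106. On the ribosomal protein list, 19 of 79 genes rose and 60 did not pass, with 29 higher when adjusted over the list alone (median 0.33, camera adjusted p = 5.47e-12; adjusted p = 0.365 with an estimated correlation). Rpl41 rose by 0.75 ± 0.117 and Rps25 by 0.60 ± 0.103. Cell cycle genes did not pass in males (0 of 34 changed, also when adjusted over the list alone; median 0.25, camera adjusted p = 0.237).

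Markers of other cells moved with these lists in males. Of 11 border-associated macrophage markers, 6 fell and 5 did not pass, with 7 lower when adjusted over the list alone (median -2.78, and -2.46 without the 2 members that have a group at 0; camera adjusted p = 0.000124; adjusted p = 0.138 with an estimated correlation). F13a1 and Pf4 changed by -4.27 ± 0.752 and -3.42 ± 0.689. Of the list, Cd209f and Lyve1 were listed at 0 in all 4 male PLX3397 libraries, against 116 to 331 and 39.1 to 152 in the 4 controls. Outside it, Cd209a, Cd209g and Cdc42ep1 were also at 0 there, against 105 to 277, 47.3 to 146 and 25.0 to 249. Cd209a is on the dendritic cell list, which did not pass (2 of 7 lower and 5 not past the test, also when adjusted over the list alone; camera adjusted p = 0.237, and 0.00169 by fry). The call of Lyve1 ended with voom weights (adjusted p = 0.134). Of 12 neutrophil markers, 9 rose and 3 did not pass, with 10 higher when adjusted over the list alone (median 4.16, and 4.08 without the 1 member with a group at 0; camera adjusted p = 2.22e-09; adjusted p = 0.0619 with an estimated correlation). S100a9 rose from 432.6 ± 349 to 7295 ± 7450, by 4.08 ± 0.676, and Ltf by 4.05 ± 0.742. Without male PLX3397 replicate 3, at 18390, the mean of S100a9 on PLX3397 was 3596 and its change 3.48 (limma adjusted p = 0.00245). Ly6g was listed at 0 in all male controls and at 24.5 to 92.1 on PLX3397, and Retnlg, above 0 in 1 control library at 5.41, read 45.3 to 399. The oligodendrocyte transcript Mbp rose by 1.13 ± 0.176, while the neuron, astrocyte and oligodendrocyte marker lists passed camera in no comparison. By fry the neuron and astrocyte lists passed in males (medians 0.52 and 1.48, adjusted p = 0.0419 and 0.044). The mitochondrial share of the normalised counts was 0.625% ± 0.0387 on PLX3397 and 0.312% ± 0.0153 on control chow, and the share of annotated pseudogenes 0.540% ± 0.0306 and 0.408% ± 0.0259 (two-sided exact permutation p = 0.0286 for each, the smallest that 4 against 4 can give; adjusted p = 0.0449 over 11 library measures).

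In all, 2289 genes changed in males, 815 higher and 1474 lower, of which 456 rose and 404 fell by more than 2-fold. Falls outside the marker lists included those of Ccdc162 (-8.46 ± 0.863), Nrarp (-7.86 ± 1.29) and Rnase10 (-6.12 ± 1.16). Other falls included Pmepa1 at -1.50 ± 0.149 and Gas6, a ligand of the AXL receptor, at -1.25 ± 0.126. The call of Nrarp ended with voom weights (adjusted p = 0.0589). Apart from Il6, Nlrp3, Nfkb1 and Il1a, the text names 59 called genes for males. All 59 had groups that did not overlap, which chance gives in 2.86% of genes. That was a condition for naming some of them, and others were chosen by a small p, so the count is no separate support. The balance of higher and lower genes depended on scaling: 1032 were higher and 1224 lower with upper-quartile scaling, 1040 and 1188 with quantile normalisation, and 1348 and 917 with equal library totals. The last moved the median of all genes by 0.156. The count was 1518 without male PLX3397 replicate 3 and male control replicate 4. Of the 35 lists, 15 passed, 10 higher and 5 lower, none with an estimated correlation, and 20 by fry. The mean per library did not overlap between the chows for 13 of the 15. The 5 that passed but are not described above each lost their call without some single library. These were immediate early genes (adjusted p = 0.0333, and 0.111 without male PLX3397 replicate 2), lipid efflux and storage (0.03, and 0.0709 without male control replicate 2), phagocytosis and complement (0.0384, and 0.165 without male PLX3397 replicate 2), the TGF-beta pathway (0.0168, and 0.0775 without male control replicate 1) and monocyte markers (0.0455, and 0.0839 without male PLX3397 replicate 3).

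**Figure D1:**
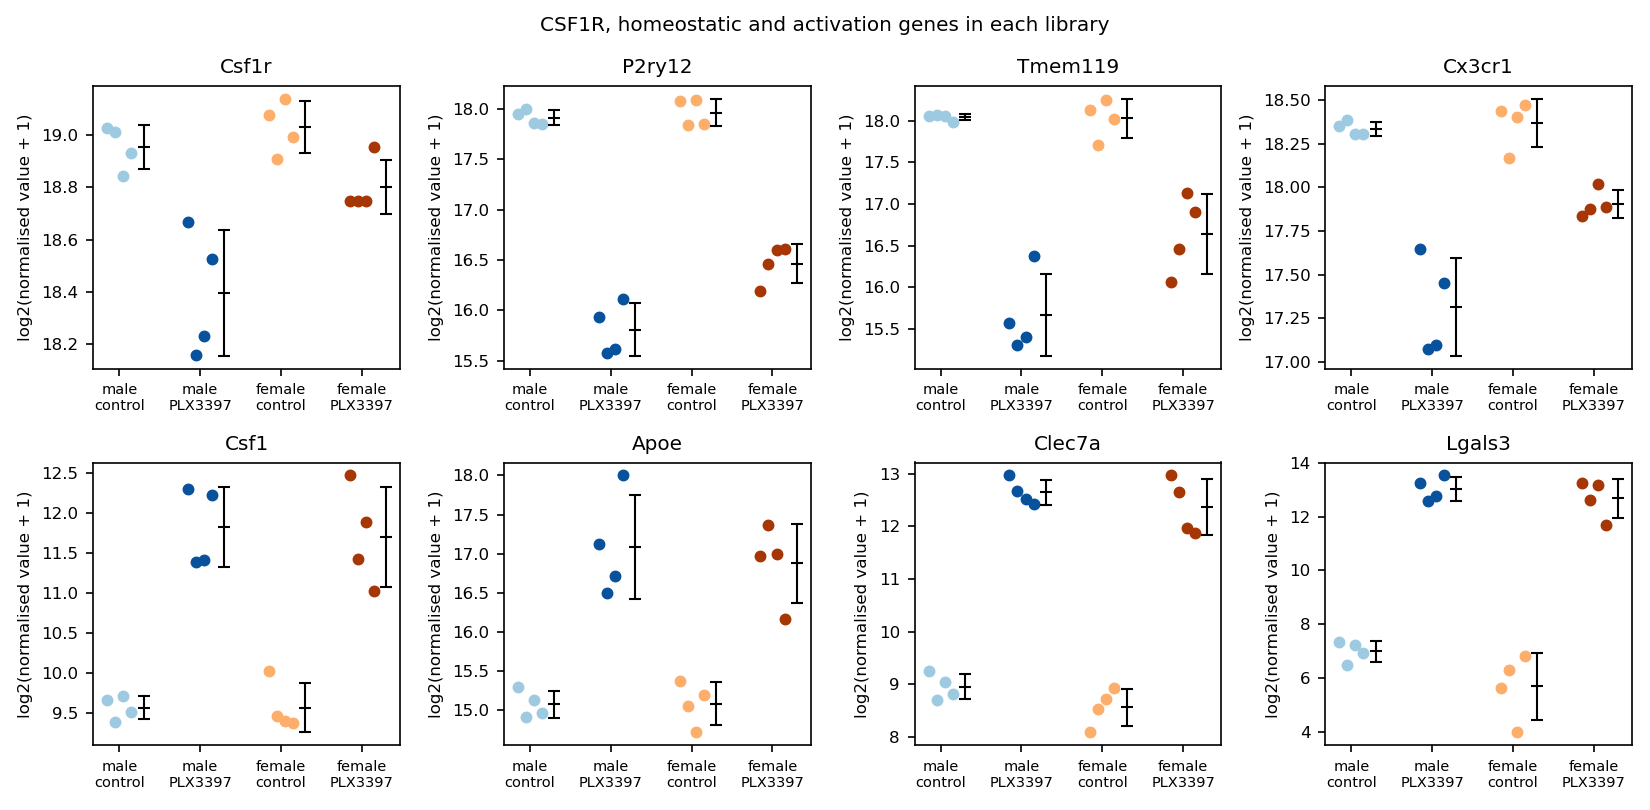
Normalised read counts (vertical axis, log2(value + 1)) of named genes in each library, with points for libraries and bars for the mean ± SD of the plotted values of a group. P2ry12 went from 247500 ± 12800 to 58080 ± 10600 in males and from 256600 ± 24300 to 90990 ± 11800 in females.

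The comparison of females on either chow asks the same of female microglia. Homeostatic transcripts fell here too. P2ry12 changed by -1.50 ± 0.116 (adjusted p = 1.15e-06), Tmem119 by -1.39 ± 0.223 (adjusted p = 0.00101), Slc2a5 by -2.27 ± 0.213 (adjusted p = 6.73e-06) and Cx3cr1 by -0.46 ± 0.104 (adjusted p = 0.0125). Csf1r went from 535500 ± 36800 to 457100 ± 33900, a change of -0.23 ± 0.0933 that did not pass (adjusted p = 0.206), and Csf1 rose by 2.14 ± 0.277 (adjusted p = 0.000167). Dusp6 and Etv5 fell by 1.68 ± 0.151 and 1.37 ± 0.222, while their list, the CSF1R axis and related kinases, had a median change of -0.03. On the homeostatic list 23 of 31 genes fell, 1 rose and 7 did not pass, and over the list alone 25 were lower and 1 higher (median -0.64, camera adjusted p = 3.32e-20; adjusted p = 0.101 with an estimated correlation). Ltc4s fell by 1.30 ± 0.146.

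The disease-associated list had 24 of 29 genes higher in females and 5 not past the test, with 27 higher when adjusted over the list alone (median 1.55, camera adjusted p = 3.58e-39). Its call also held with an estimated correlation (adjusted p = 0.0233), as no other list of either PLX3397 response did. Lgals3 rose by 7.00 ± 0.482, Clec7a by 3.80 ± 0.236, Lpl by 2.59 ± 0.295, Lyz2 by 2.08 ± 0.143, Cd63 by 1.99 ± 0.141 and Apoe by 1.79 ± 0.276. Trem2 changed by 0.42 ± 0.119 (adjusted p = 0.0482), a call that ended without any of 11 single libraries, with an adjusted p of up to 0.146 without female control replicate 4. The cholesterol esterification gene Soat1, the stress genes Gadd45b and Atf3, and Gdf15 rose by 1.30 ± 0.162, 4.29 ± 0.548, 1.73 ± 0.238 and 6.65 ± 0.985. Cd44 and Il1rn rose by 6.28 ± 1.22 and 6.18 ± 1.02, both without a call when weighted by depth with voom (adjusted p = 0.19 and 0.0875).

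Among immune lists in females, interferon response genes had 14 of 36 members higher and 22 not past the test, with 17 higher when adjusted over the list alone (median 0.92, camera adjusted p = 1.18e-11; adjusted p = 0.101 with an estimated correlation). Ifitm3 and Slfn2 rose by 1.74 ± 0.265 and 1.15 ± 0.197. Inflammatory genes had 13 of 26 higher, 2 lower and 11 not past the test, and over the list alone 16 higher and 4 lower (median 0.83, camera adjusted p = 1.39e-10; adjusted p = 0.0808 with an estimated correlation). Il1b, Ccl4 and Cxcl16 rose by 3.91 ± 0.393, 3.05 ± 0.276 and 2.01 ± 0.19. The 2 members that fell were Nlrp3 (-0.98) and Nfkb1 (-0.62), with limma adjusted p = 0.013 and 0.00166. On the antigen presentation list 7 of 24 genes rose and 17 did not pass, and over the list alone 10 were higher and 1 lower (median 0.21, camera adjusted p = 0.00075; adjusted p = 0.305 with an estimated correlation). H2-D1 and H2-K1 rose by 1.26 ± 0.136 and 1.05 ± 0.122, and the list lost its call without female PLX3397 replicate 2 (adjusted p = 0.0571).

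Lysosome genes rose in 23 of 52 cases in females and 29 did not pass, with 33 higher when adjusted over the list alone (median 0.41, camera adjusted p = 6.63e-19; adjusted p = 0.133 with an estimated correlation). Ctsb and Ctsa rose by 1.55 ± 0.129 and 0.80 ± 0.0878. Of 34 cell cycle genes 4 fell and 30 did not pass, and over the list alone 6 were lower and 1 higher (median -0.90, camera adjusted p = 0.000317; adjusted p = 0.133 with an estimated correlation). The mitotic kinase gene Plk1 read 92.9 to 142 in female controls and 0 to 1.03 on PLX3397 (-6.57 ± 0.9), and the cyclin gene Ccnb2 fell by 4.29 ± 0.808, both without a call under voom (adjusted p = 0.2 and 0.0746). Rrm2, at 35.3 to 129 in controls and 0 to 1.96 on PLX3397, lost its call (adjusted p = 0.0409) without any of 8 single libraries, reaching 0.11 without female control replicate 1. Proteasome genes did not pass in females (0 of 40 changed, also when adjusted over the list alone; camera adjusted p = 0.318). Mitochondrially encoded genes had 1 of 13 higher and 12 not past the test, with 6 higher when adjusted over the list alone (median 0.34, camera adjusted p = 2.86e-05; adjusted p = 0.29 with an estimated correlation). That gene, mt-Co2, rose by 0.49 ± 0.119 (adjusted p = 0.0217), a call that ended without female PLX3397 replicate 1 (0.0803) and without each of 3 other libraries. Of 75 nuclear-encoded respiratory chain genes 3 rose and 72 did not pass, with 0 when adjusted over the list alone (median 0.16, camera adjusted p = 5.12e-05; adjusted p = 0.443 with an estimated correlation). Ribosomal protein genes had 7 of 79 higher and 72 not past the test, with 15 higher when adjusted over the list alone (median 0.31, camera adjusted p = 2.28e-15; adjusted p = 0.248 with an estimated correlation). Rps25 rose by 0.50 ± 0.103. The glycolytic genes Tpi1 and Aldoa rose by 1.10 ± 0.14 and 0.73 ± 0.125.

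Marker lists of other cells moved in females as well. Of 11 border-associated macrophage markers 4 fell and 7 did not pass, with 5 lower when adjusted over the list alone (median -2.51, camera adjusted p = 2.08e-05; adjusted p = 0.101 with an estimated correlation). Pf4 and F13a1 fell by 4.20 ± 0.689 and 3.53 ± 0.752. Cd209f of this list and Cd209a of the dendritic cell list fell by 6.48 ± 1.11 and 6.59 ± 0.835, to 0 in every female PLX3397 library but replicate 3, where they read 115 and 28.7. Of 12 neutrophil markers 6 rose and 6 did not pass, as when adjusted over the list alone (median 3.65, and 0.79 without the 7 members that have a group at 0; camera adjusted p = 6.6e-08; adjusted p = 0.0808 with an estimated correlation). S100a8, S100a9 and Ltf were listed at 0 in all 4 female controls and read 111 to 499, 147 to 712 and 72.3 to 440 on PLX3397, and Ngp rose from at most 1.30 to between 183 and 1142. These neutrophil calls ended with voom weights, for the list (adjusted p = 0.136) and for the 4 genes (adjusted p = 0.436 to 0.561). Of 5 erythroid genes 1 fell and 4 did not pass, with 3 lower when adjusted over the list alone (median -5.64, and 0.48 without the 4 members with a group at 0; camera adjusted p = 0.00951; adjusted p = 0.239 with an estimated correlation, and 0.204 with voom weights). Hbb-bs was listed at 0 in all female PLX3397 libraries and read 12.0 to 387 in controls, a call (adjusted p = 0.0403) that ended without any of 8 single libraries, with up to 0.114 without female control replicate 3. Mbp rose by 0.86 ± 0.176. The mitochondrial share was 0.395% ± 0.0449 on PLX3397 and 0.307% ± 0.0361 on control chow, and the pseudogene share 0.430% ± 0.0181 and 0.379% ± 0.0221 (two-sided exact permutation p = 0.0286 for each; adjusted p = 0.0629 over 11 measures).

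In all, 1047 genes changed in females, 524 higher and 523 lower, of which 272 rose and 212 fell by more than 2-fold. Nrarp fell by 5.44 ± 1.29, without a call when female control replicate 3 was left out (adjusted p = 0.0509), and Alb was listed at 0 in all PLX3397 libraries and at 47.4 to 119 in controls. Syt6 fell from 96.0 to 140.3 in controls to 0 in all PLX3397 libraries but replicate 4, at 17.0. Of the 51 named called genes besides Nlrp3 and Nfkb1, 50 had groups that did not overlap, Trem2 being the exception, a separation that the naming rule favoured. Of the 35 lists, 18 passed, 14 higher and 4 lower, 1 with an estimated correlation and 22 by fry. The mean per library did not overlap between the chows for 12 of these 18 lists. Those that overlapped included ribosomal proteins, nuclear-encoded oxidative phosphorylation, antigen presentation and border-associated macrophage markers.

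**Figure D2:**
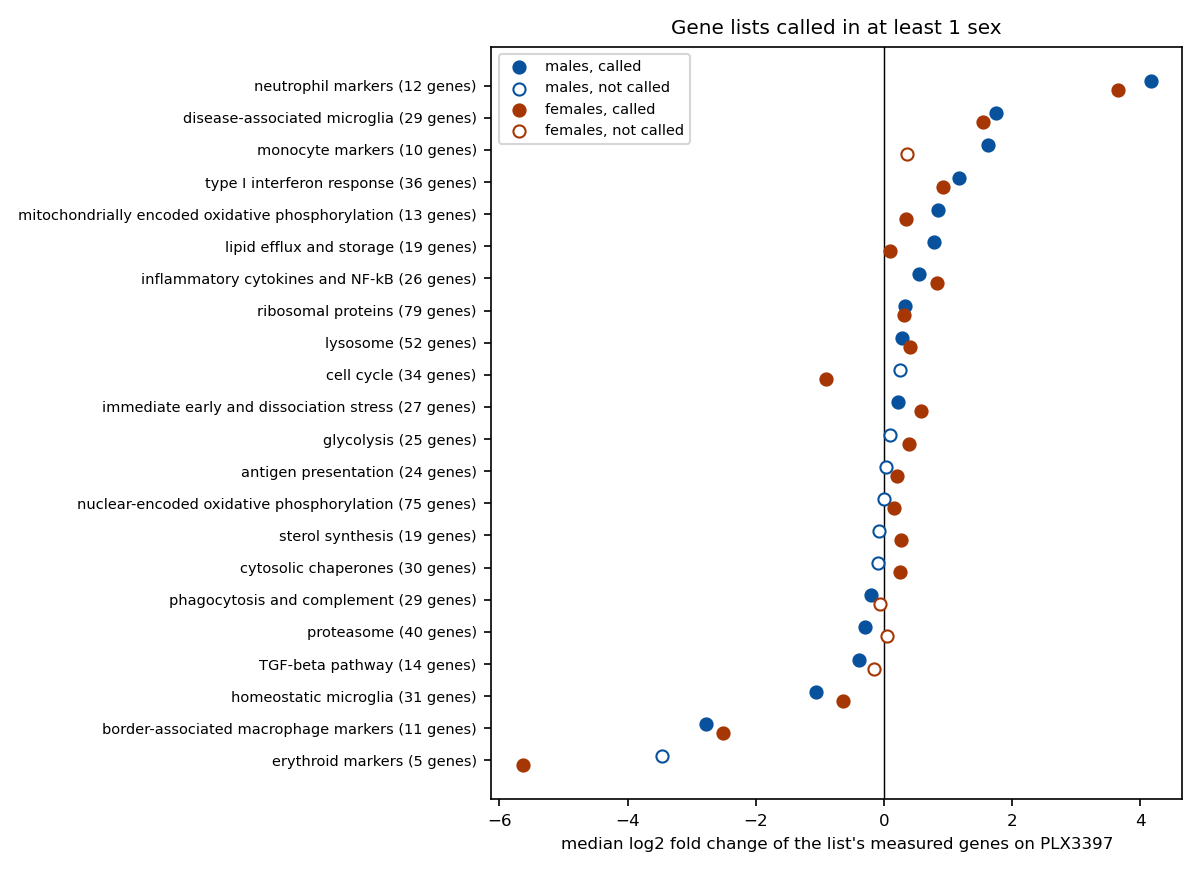
Median log2 fold change on PLX3397 (horizontal axis, log2(value + 1) scale) of the lists that passed camera in at least 1 sex, with 1 point per list and sex, filled where the list passed. Homeostatic genes had medians of -1.06 in males and -0.64 in females, and disease-associated genes 1.74 and 1.55.

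The responses of the sexes overlapped. Of the called genes, 338 were higher in both sexes, where independent lists would share 21.8, and 408 were lower in both (39.3 expected), with 1 called in opposite directions. Fold changes correlated across all tested genes with Pearson r = 0.437, and across genes called in either sex with r = 0.755; genes are not independent replicates. Of the male calls 88.1% had the same sign in females, and of the female calls 95.7% had the same sign in males. The male and female comparisons share no control library.

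The test of the difference between the responses, females minus males, asks directly whether the effect of PLX3397 depended on sex. By limma 0 genes passed, and 2010 had an unadjusted p under 0.05. With voom weights 0 passed, and with a pseudocount of 5 there was 1. For P2ry12 the difference was 0.61 ± 0.163 (adjusted p = 0.229), for Cx3cr1 0.56 ± 0.147 (adjusted p = 0.229), for Tmem119 0.99 ± 0.315 (adjusted p = 0.293), for P2ry13 0.94 ± 0.23 (adjusted p = 0.208), for Lpcat2 0.53 ± 0.116 (adjusted p = 0.185) and for Csf1r 0.33 ± 0.132 (adjusted p = 0.399). The lowest adjusted p was 0.133, shared by Slc2a5 (1.58 ± 0.301), Gas6 (0.91 ± 0.178) and Plk1 (-7.27 ± 1.27) among others. Slc2a5 and Gas6 passed without male PLX3397 replicate 4 (adjusted p = 0.0338 and 0.0368), and Plk1 without male control replicate 4 (adjusted p = 0.00468). Leaving out that PLX3397 library gave 6 genes, female PLX3397 replicate 4 gave 3, male control replicate 1 gave 2, and each of male PLX3397 replicates 1 and 3, male control replicate 4 and female PLX3397 replicate 2 gave 1. Of the 1542 genes called in males alone, 723 had an unadjusted interaction p under 0.05 and 0 an adjusted one, so a call in 1 sex alone was not shown to be a difference between the sexes.

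Gene lists did differ in response under the preset correlation, 10 of 35 by camera, but 0 with an estimated correlation and 0 by fry. By exact permutation of the mean per library, which could have passed lists in this comparison, 0 passed. Homeostatic genes fell less in females, with a median difference of 0.42 (0 of 31 genes called, 13 higher when adjusted over the list alone; camera adjusted p = 6.53e-12; adjusted p = 0.38 with an estimated correlation). Proteasome genes were higher in the female response by a median of 0.34 (0 of 40 called, 5 higher when adjusted over the list alone; camera adjusted p = 3.79e-09; adjusted p = 0.438 with an estimated correlation), with Adrm1 at 0.66 ± 0.156 and Psmd5 at 0.94 ± 0.245 (adjusted p = 0.208 and 0.228). Mitochondrially encoded genes had a median difference of -0.52 (0 of 13 called, 9 lower when adjusted over the list alone; camera adjusted p = 3.79e-09; adjusted p = 0.38 with an estimated correlation), with mt-Nd4 at -0.74 ± 0.16 (adjusted p = 0.185). Cell cycle genes had a median difference of -1.04 (0 of 34 called, 1 lower when adjusted over the list alone; camera adjusted p = 4.92e-06; adjusted p = 0.332 with an estimated correlation). The unfolded protein and integrated stress response list differed by 0.36 (0 of 30 called, also when adjusted over the list alone; camera adjusted p = 0.000172; adjusted p = 0.519 with an estimated correlation). The lysosome list differed by 0.15 (0 of 52 called, also when adjusted over the list alone; camera adjusted p = 0.000242; adjusted p = 0.713 with an estimated correlation), but by -0.04 with quantile normalisation (adjusted p = 0.98). It differed by -0.01 with equal library totals, where camera still ranked it above other genes (adjusted p = 0.0227). The medians of the homeostatic, proteasome, unfolded protein, mitochondrially encoded and cell cycle lists kept their signs under each scaling, although equal library totals moved the median of all genes in this test by -0.163 and upper-quartile scaling by -0.1. The mitochondrial share of the libraries, which rose more in males, gave a two-sided exact permutation p = 0.0167 for the same difference (adjusted p = 0.108 over 11 measures).

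**Figure D3:**
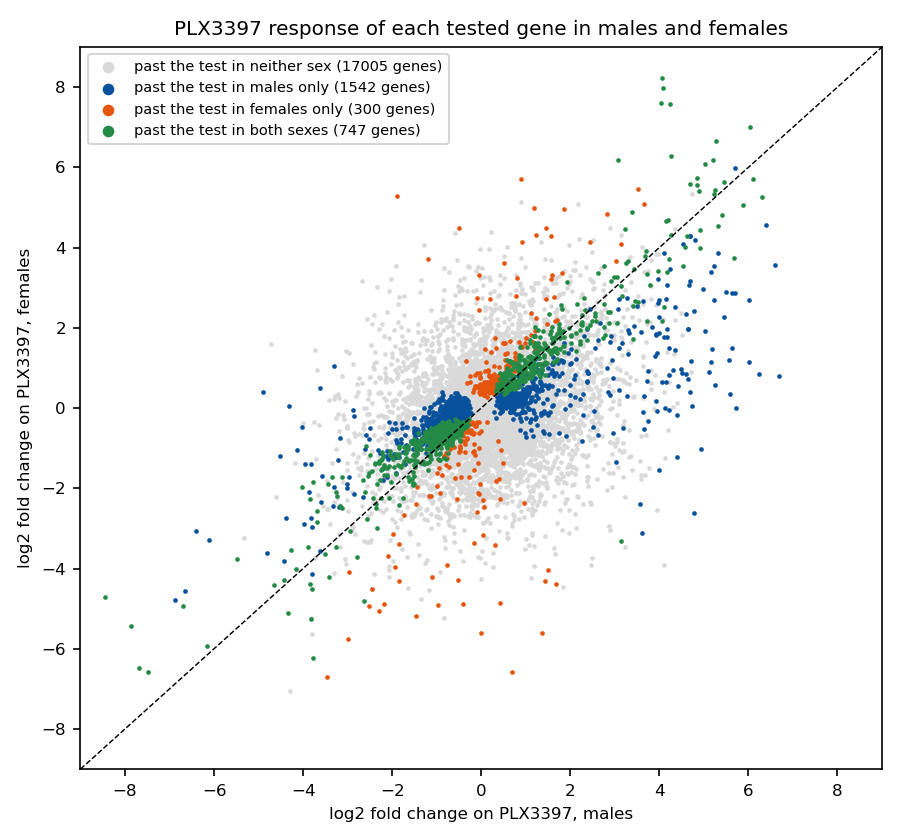
Log2 fold change on PLX3397 in females (vertical axis) against that in males (horizontal axis), both on the log2(value + 1) scale, with 1 point per tested gene and a dashed line of equal change. Of the genes, 1542 were called in males alone, 300 in females alone and 746 in both in the same direction.

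On control chow, 13 genes differed between the sexes, 3 higher and 10 lower in females. Xist, the RNA that coats the inactive X chromosome, was 7.42 ± 0.738 higher in females (adjusted p = 6.53e-05). The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were lower by -8.11 ± 0.396, -7.20 ± 0.283, -3.60 ± 0.271 and -3.44 ± 0.2. Female libraries still held 127 ± 6.89 for Kdm5d and 58.6 ± 21.0 for Uty, genes whose reads can be shared with X-linked homologues. Xist read 516 in male control replicate 4 and 14.7 to 31.4 in the other 3 male controls. Tsix, antisense to Xist and not told apart from it in reads without strand, differed by 8.22 ± 1.34 (adjusted p = 0.0209), a call that ended without any of 7 single libraries, with up to 0.112 without male control replicate 3. The X inactivation list passed (1 of 9 higher and 8 not past the test, 4 higher when adjusted over the list alone; median 0.48, camera adjusted p = 2.95e-08), also with an estimated correlation (adjusted p = 0.00146). Ddx3x differed by 0.48 ± 0.0859 (adjusted p = 0.0515).

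The other genes named for control chow were neutrophil genes. Of 12 neutrophil markers 5 were lower in females and 7 did not pass, with 6 lower when adjusted over the list alone (median -3.33, and -0.94 without members that have a group at 0; camera adjusted p = 1.11e-14), also with an estimated correlation (adjusted p = 0.00938). S100a8, S100a9, Ltf and Lcn2 were listed at 0 in all female controls and read 35.8 to 687, 102 to 829, 51.3 to 562 and 34.3 to 280 in male controls, and Ngp was lower in females by -7.81 ± 0.955. With voom weights none of these 5 genes passed (adjusted p = 0.962) and neither did the list (0.051). P2ry12 and Csf1r differed by 0.05 ± 0.116 and 0.08 ± 0.0933 (adjusted p = 0.996 and 0.988). By voom 7 genes differed in all. In the main fit 1017 genes had an unadjusted p under 0.05, and 20 passed without male control replicate 1. Of the 35 lists 5 passed, 2 of them, X inactivation and neutrophil markers, with an estimated correlation and by fry. Among the 5, only these 2 had means per library that did not overlap between the sexes on control chow. Cell cycle genes passed there as higher in females (0 of 34 called, also when adjusted over the list alone; median 0.37, camera adjusted p = 0.00691; adjusted p = 0.653 with an estimated correlation), though not without male control replicate 3 (0.104) or female control replicate 1 (0.11). The count of lists was 2 without female control replicate 1, 15 without female control replicate 2, and 3 without female control replicate 3 or male control replicate 3.

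On PLX3397 chow, the comparison of females with males asks how the surviving microglia differed. Homeostatic transcripts stood higher in females. Slc2a5 was at 10460 ± 2950 in females and 3352 ± 1250 in males, a difference of 1.67 ± 0.213 (adjusted p = 0.000899). P2ry12 was higher by 0.66 ± 0.116 (adjusted p = 0.00695), Cx3cr1 by 0.59 ± 0.104 (adjusted p = 0.00695), Adgrg1 by 0.69 ± 0.121 and Lpcat2 by 0.48 ± 0.0818. Gas6, the TGF-beta repressor gene Ski and the sterol synthesis gene Sc5d were higher by 0.98 ± 0.126, 0.99 ± 0.126 and 1.21 ± 0.202, and Tlr5 and Smpdl3b by 2.09 ± 0.289 and 1.67 ± 0.243. Fitted to the groups compared alone, the calls of P2ry12, Cx3cr1, Adgrg1, Lpcat2, Tlr5 and Smpdl3b ended (limma adjusted p = 0.0608 to 0.074). That of Cx3cr1 also ended with quantile normalisation (0.0734). Csf1r and Tmem119 were higher by 0.40 ± 0.0933 and 0.97 ± 0.223 (adjusted p = 0.0225 and 0.0212), but each lost its call without male PLX3397 replicate 2 (0.0765 and 0.0811), male PLX3397 replicate 3 or female PLX3397 replicate 4, and Tmem119 also without female PLX3397 replicate 3. The Csf1r call depended on scaling as well, and ended with upper-quartile scaling (0.0606), quantile normalisation (0.228) and equal library totals (0.0638). It ended without a filter too (0.0715). For Csf1r and Tmem119 alike, the call ended when fitted to the groups compared alone (0.124 and 0.12), with voom weights and equal totals (0.0792 and 0.0738), and without the doubted pair of male control replicate 4 and male PLX3397 replicate 3 (0.0919 and 0.0834). Of the 40 named called genes, 39 had groups that did not overlap, Tmem119 being the exception, a separation that the naming rule favoured. Less firm still were Fcna, Efnb2, C1ra and Cavin1 (4.99 ± 1.16, 3.53 ± 0.899, 1.74 ± 0.456 and 4.89 ± 1.37), which lost their calls without 3, 7, 6 and 12 single libraries, with adjusted p of up to 0.0686, 0.0911, 0.109 and 0.131.

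Of the 31 homeostatic genes 18 were higher in females on PLX3397 and 13 did not pass, with 23 higher when adjusted over the list alone (median 0.47, camera adjusted p = 1.66e-14; adjusted p = 0.204 with an estimated correlation). Proteasome genes were higher in 10 of 40 cases and 30 did not pass, with 22 higher when adjusted over the list alone (median 0.34, camera adjusted p = 1.19e-11; adjusted p = 0.204 with an estimated correlation). Adrm1 and Psmd3 differed by 0.58 ± 0.111 and 0.55 ± 0.104. On the unfolded protein and integrated stress response list 10 of 30 genes were higher and 20 did not pass, and over the list alone 18 were higher and 1 lower (median 0.39, camera adjusted p = 2.5e-07; adjusted p = 0.215 with an estimated correlation), with Edem1, which acts in the degradation of misfolded proteins, at 0.59 ± 0.118. Mitochondrially encoded genes were lower in 8 of 13 cases and 5 did not pass, with 12 lower when adjusted over the list alone (median -0.48, camera adjusted p = 3.67e-08; adjusted p = 0.215 with an estimated correlation). The genes mt-Nd4 and mt-Co1 differed by -0.60 ± 0.113 and -0.54 ± 0.106. Both genes and the list lost their calls once the trend over GC content and length was removed (adjusted p = 0.199, 0.0652 and 0.113). Lysosome genes were higher in 8 of 52 cases and 44 did not pass, with 11 higher when adjusted over the list alone (median 0.19, camera adjusted p = 2.76e-06; adjusted p = 0.414 with an estimated correlation), but their median was -0.05 with quantile normalisation (adjusted p = 0.858). It was -0.01 with equal library totals, where camera still ranked them above other genes (adjusted p = 0.00335). Disease-associated genes did not pass (median -0.05, adjusted p = 0.896), except with quantile normalisation (median -0.26, adjusted p = 0.00517). Nor did ribosomal protein genes (median -0.01, adjusted p = 0.711), whose medians were -0.22 with equal library totals (adjusted p = 0.00153), -0.17 with upper-quartile scaling (0.0172) and -0.17 with quantile normalisation (8.56e-07), and which passed without male PLX3397 replicate 2 (0.0276) or female PLX3397 replicate 3 (0.032).

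Also lower in females on PLX3397 were cell cycle, neutrophil and monocyte genes. Of 34 cell cycle genes 3 were lower and 31 did not pass, with 5 lower when adjusted over the list alone (median -0.56, camera adjusted p = 0.00582; adjusted p = 0.239 with an estimated correlation, and 0.0506 with voom weights). The proliferation marker Mki67 read 57.0 to 159 in males and 0 to 4.37 in females, and Plk1 32.7 to 133 and 0 to 1.03, both without a call under voom (adjusted p = 0.169 and 0.211). Ccnb2 differed by -3.10 ± 0.808 (adjusted p = 0.0377), a call that ended without any of 5 single libraries, with up to 0.108 without male PLX3397 replicate 3. Of 12 neutrophil markers 9 were lower and 3 did not pass, with all 12 lower when adjusted over the list alone (median -4.28, camera adjusted p = 2.85e-11; adjusted p = 0.0605 with an estimated correlation). S100a9, S100a8 and Ltf differed by -4.39 ± 0.676, -4.33 ± 0.795 and -3.84 ± 0.742, Retnlg by -6.06 ± 0.939, Slpi by -5.63 ± 0.975 and Mmp9 by -6.84 ± 1.54. Mmp9 lost its call (adjusted p = 0.0199) without male PLX3397 replicates 2 or 3 or female PLX3397 replicates 2 or 3, with up to 0.0654. Of 10 monocyte markers 1 was lower and 9 did not pass, as when adjusted over the list alone (median -0.88, camera adjusted p = 0.0232; adjusted p = 0.204 with an estimated correlation). That call ended without female PLX3397 replicate 3 (adjusted p = 0.0634), with upper-quartile scaling (0.0673), with quantile normalisation (0.0626) and with equal library totals (0.0976). Acap1 and Padi4 were listed at 0 in all 8 female libraries and read 60.9 to 216 and 25.6 to 145 in males on PLX3397. In male controls they read 0 to 4.68 and 0 to 18.0. Like S100a8 and S100a9, both read higher in replicates 3 and 4 than in the other males on PLX3397. Whether their reads came from microglia was not tested. Xist and Tsix were higher in females by 8.60 ± 0.738 and 10.07 ± 1.34, the X-linked genes Ddx3x and Eif2s3x by 0.76 ± 0.0859 and 1.16 ± 0.201. Ddx3y, Eif2s3y, Uty and Kdm5d were lower by -8.46 ± 0.396, -7.59 ± 0.283, -3.92 ± 0.271 and -3.43 ± 0.2. The mitochondrial share was higher in males (0.625% against 0.395%, two-sided exact permutation p = 0.0286; adjusted p = 0.0449), and the library total lower, with the same p.

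In all, 1064 genes differed by sex on PLX3397, 838 higher and 226 lower in females, of which 52 and 115 differed by more than 2-fold. This count rested on the spread that all 4 groups gave together: with a fit to these 8 libraries alone 44 genes passed (14 on control chow, fitted likewise), 43 of them among the 1064, and of the 40 named genes 20 kept their calls. It also rested on scaling and on single libraries, with 265 higher and 341 lower under upper-quartile scaling, 246 and 221 under quantile normalisation and 196 and 375 with equal library totals, which moved the median of all genes by -0.149, 0.0217 and -0.196. There were 332, 469, 677, 480 and 709 genes without male PLX3397 replicate 2 or 3 or female PLX3397 replicate 2, 3 or 4. The 16 named genes that kept their calls under every alternative listed in the methods were Xist, Tsix, Ddx3x, Eif2s3x, Ddx3y, Eif2s3y, Kdm5d, Uty, Slc2a5, Gas6, Ski, Sc5d, S100a8, S100a9, Acap1 and Padi4. A fit with the mitochondrial share as a covariate, described below, was not among those alternatives. With it only 3 of the 1064 calls held, so most of the 16 lost theirs. Of the 35 lists 19 passed, 15 higher and 4 lower, 0 with an estimated correlation, 17 by fry and 11 with quantile normalisation. The mean per library did not overlap between the sexes for 9 of these 19 lists. Those that overlapped included the lysosome, cytosolic chaperones, glycolysis, sterol synthesis, and phagocytosis and complement.

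**Figure D4:**
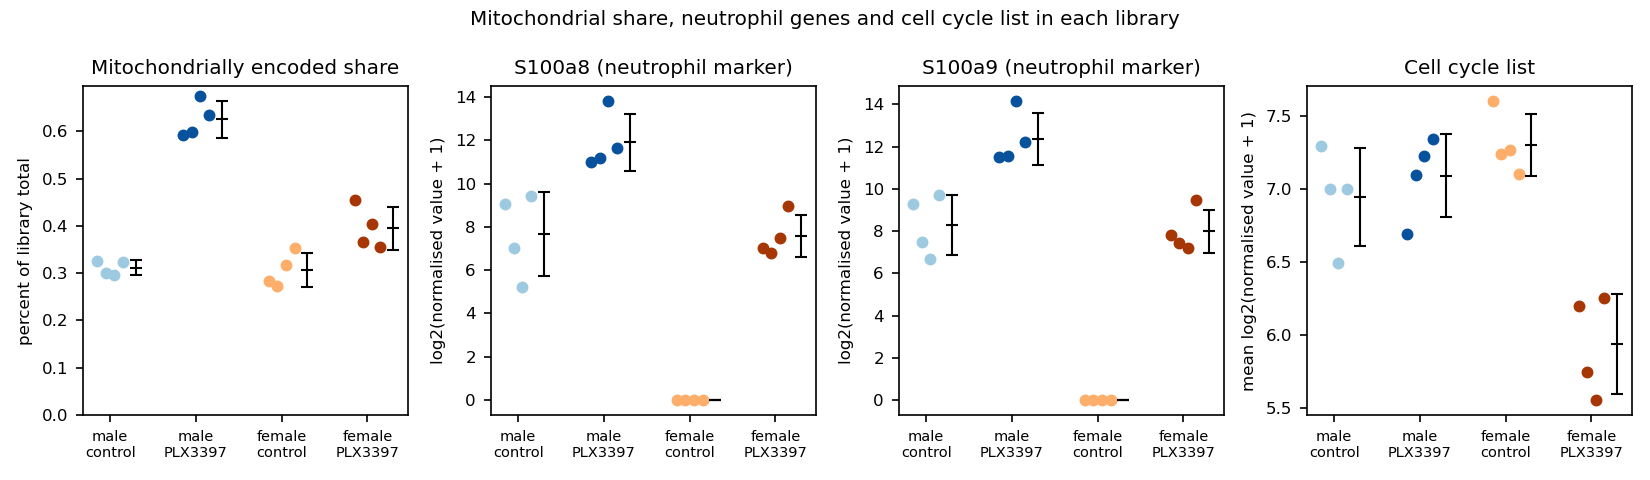
Mitochondrially encoded share (percent of the library total), the neutrophil genes S100a8 and S100a9 (log2(value + 1)) and the mean of the cell cycle list (log2(value + 1)) per library, with points for the 4 libraries of a group and bars for the mean ± SD of the plotted values. The mitochondrial share was 0.625% ± 0.0387 in males on PLX3397 and 0.395% ± 0.0449 in females on PLX3397.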

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

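Of the tests below, those of blood in general and of a single library in the cell cycle pattern were chosen after the result was seen. The alternatives with voom weights, equal totals and the GC and length trend removed were also added then. Within groups of 4, the highest or lowest library stood apart by Dixon's ratio in 42 of 389 groups (34 of 313 for genes, 6 of 60 for list scores and 2 of 16 for library measures). Chance gives about 1 in 20 groups, and in 18 of the 42 the other 3 libraries were at 0.

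Among transcripts of microglia, 1 library stood apart for Csf1r in female PLX3397 replicate 4 (508000, others 439800 to 440400), Csf1 in female control replicate 1 (1041), Tmem119 in male control replicate 4 (259600). It did so for Slc2a5 in male control replicate 3 (42180), P2ry13 in female PLX3397 replicate 3 (58380), Ccnd1 in male PLX3397 replicate 4 (526.7), and Cst7 and Lpl in male control replicate 3 (459.2 and 754). The others were Ctsb in male control replicate 1 (155200), H2-K1 in female control replicate 2 (12290) and Gas6 in female control replicate 1 (14920). Disease-associated scores stood highest in male control replicate 1 (11.74) and female control replicate 3 (11.8), and the ribosomal protein score in male control replicate 1 (11.15). Ribosomal protein genes held 0.493% of female control replicate 2, and pseudogenes 0.457% of female PLX3397 replicate 1. Uty was highest in male control replicate 2 (811.4) and Tsix above 0 among males on PLX3397 in replicate 4 alone (47.92).

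Border-associated macrophage scores stood apart in male PLX3397 replicate 1 (4.222), female control replicate 3 (6.101) and female PLX3397 replicate 3 (6.635, others 4.316 to 4.374). Genes of that list did so for Cd209f in female PLX3397 replicate 3 (114.8, others at 0), Lyve1 in male control replicate 1 (39.07) and F13a1 in female control replicate 3 (241.8). The dendritic cell marker Cd209a did so in female PLX3397 replicate 3 (28.66, others at 0) and female control replicate 1 (306.7). For the other genes named, the library apart was the highest over 3 libraries at 0. These were Mmp9 in male control replicate 2 (94.65) and female PLX3397 replicate 1 (62.34), Retnlg in male control replicate 3 (5.41) and female PLX3397 replicate 3 (9.175), and Nrarp and Rnase10 in male PLX3397 replicate 2 (49.1 and 26.82). So it was for Ngp in female control replicate 3 (1.296), Cd44 in female control replicate 2 (29.88), and Syt6, Rrm2, Plk1 and Slpi in female PLX3397 replicate 4 (17.01, 1.964, 1.027 and 4.001). The last were Mki67 in female PLX3397 replicate 2 (4.369), Fcna in male PLX3397 replicate 2 (2.406) and Cavin1 in male PLX3397 replicate 1 (3.057). Plk1 was also lowest in male control replicate 4 (1.579).

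The response to PLX3397 differed by sex, females minus males, for 10 lists by camera. Of these 0 passed with an estimated correlation (lowest adjusted p = 0.332), by fry or by exact permutation of the mean per library. The median differences were 0.418 for homeostatic microglia, -1.04 for the cell cycle, 0.153 for the lysosome, and 0.341 for the proteasome. They were 0.244 for cytosolic chaperones, 0.355 for the unfolded protein response, 0.147 for nuclear-encoded and -0.524 for mitochondrially encoded oxidative phosphorylation, 0.0692 for mitochondrial biogenesis and 0.274 for phagocytosis and complement. Chaperones lost the call without female PLX3397 replicate 4 (adjusted p = 0.0545), and nuclear-encoded oxidative phosphorylation without male PLX3397 replicate 2 (0.372), female PLX3397 replicate 3 (0.0906) or female control replicate 2 (0.431). Mitochondrial biogenesis lost it without 9 single libraries, with up to 0.205 without male PLX3397 replicate 2. Medians turned to -0.04 for the lysosome, -0.04 for mitochondrial biogenesis and -0.0089 for phagocytosis with quantile normalisation, and to -0.02 for nuclear-encoded oxidative phosphorylation with equal library totals.

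Neutrophil transcripts were higher on PLX3397 and in males. Blood carried over in general stays open: 0 of 6 tests of T and NK, B and erythroid lists, of 5 measured genes each, passed as higher on PLX3397, but monocyte markers did in males (camera adjusted p = 0.0455, a call that ended without any of 7 single libraries, with up to 0.0839 without male PLX3397 replicate 3) and were lower in females than in males on PLX3397 (0.0232, and 0.0634 without female PLX3397 replicate 3), though with an estimated correlation neither passed (0.172 and 0.204). Erythroid genes passed as lower in females (median -5.64, and 0.48 without the 4 members with a group at 0), and B cell genes as lower in males by fry (adjusted p = 0.000581). Neutrophils carried over into the sort stay open too. With group means removed, the 12 genes had a median pairwise correlation of 0.128 over the 16 libraries (-0.00228 to 0.299 without 1 library). The 1000 random lists had a median of 7.81e-05 and at most 0.186, and over 0.5 was predicted of carry-over. Some of the 12, such as S100a8, were at 0 in all female controls and could not vary there. Of the 12 genes, 2 were also abundant where S100a8 was at 0: Csf3r had a mean of 33800 over all libraries and Cxcr2 of 236, and the most abundant of the others, S100a9, had 2010 (918.3 without male PLX3397 replicate 3), with S100a8 at 14420 in male PLX3397 replicate 3 and 2020 to 3184 in the other 3 libraries, as carry-over may give. S100a9, Ngp, Ltf and Lcn2 likewise read highest in male PLX3397 replicate 3, at 18390, 17560, 10020 and 3739. Like S100a8, they also read highest in female PLX3397 replicate 4 among females on PLX3397 (S100a9 at 711.7, others 147.4 to 225.9). In male controls all of these read higher in replicates 1 and 4 than in replicates 2 and 3. Other members did not follow, as Mmp9, Ly6g and Retnlg were at 0 in female PLX3397 replicate 4. The sort would remove neutrophils if its gate excluded them, and a difference in microglia by sex or drug was not tested apart from carry-over.

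Many more genes differed by sex on PLX3397 (1064) than on control chow (13), but with each comparison fitted to its own 8 libraries the counts were 44 and 14, and without male PLX3397 replicate 2 or 3 or female PLX3397 replicate 2, 3 or 4 the 1064 became 332, 469, 677, 480 and 709. A GC or length trend between libraries is argued against as the whole cause, since 744 of the 1064 calls held with the trend removed. RNA quality of the male PLX3397 libraries stays open: with the mitochondrial share as a covariate 3 calls held, as few as was predicted in writing if quality were the cause. It is not taken as shown, by a condition on size outside that prediction, since the median size of the calls went from 0.613 to 0.621 and their SE from 0.139 to 0.396, with 94.6% of the share explained by the groups. A larger response of males along the direction the sexes share stays open too (score changes of 1.2 in males and 1.01 in females, two-sided exact permutation p = 0.0886 over 4900 relabellings), as does a sex difference in microglia, which was not tested, and these cannot be told apart here.

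Cell cycle transcripts were lower in females on PLX3397 than the male response would give (median difference -1.04). Values near the floor stay open as a cause. The median was -0.757 with a pseudocount of 5 over the 29 genes with a mean of at least 50. That mean is over all libraries, so it keeps genes such as Plk1, at 0 to 1.03 in females on PLX3397. With voom weights the calls of Plk1 and Mki67 between the sexes on PLX3397 ended (limma adjusted p = 0.211 and 0.169), and so did that of the list. A single library is argued against as the cause, as the size did not go below that of -0.682 without any 1 library and the highest adjusted p was 0.00013. A difference by sex stays open, as it was not tested apart from these, and the list did not pass with an estimated correlation (adjusted p = 0.332) or by fry (0.0759).

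Other splits of the same 8 libraries argue against chance for the counts in males and in females. In each comparison only the real one of 35 splits, the smallest share they can give, gave as many genes. There were 2289 in males against at most 4, and 1047 in females against at most 2. Between the sexes there were 13 on control chow against at most 2, and 1064 on PLX3397 against at most 4. Between the sexes the real split had to stand out. Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty were called in both and are more genes than any other split gave. Those counts therefore do not settle chance for the other genes. For genes whose response differed by sex, 0 by limma (2010 at an unadjusted p under 0.05, and 0 with voom weights), other assignments of sex say nothing about chance, since any count reaches 0: 100 of 100 did, the real one among them, and the others gave at most 7 genes.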

How the results depend on the processing

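Added after seeing the data were the tests with voom weights, equal library totals, both together, the GC and length trend removed, the mean per library with exact permutation, and the doubted pair (male control replicate 4 and male PLX3397 replicate 3) left out, and so was the simulated recovery by level of expression. The planned count tests were not run, because whole reads were not recovered. Of the values of named genes, 11723 kept their side of the threshold without 1 library, 459 lost it, 74 gained it and 0 reversed; under other settings these were 9991, 516, 141 and 0. For lists they were 2700, 50, 49 and 1, and 2557, 159, 65 and 4. Male calls (2289) were 1724 to 2312 without 1 library and 1518 without the doubted pair, and female calls (1047) 772 to 1143. The cause of these and later changes was not tested. Genes whose response differed (0) were 0 to 6 without 1 library (6 without male PLX3397 replicate 4), 1 with pseudocount 5 and 2 without the doubted pair. Sex differences on control chow (13) were 11 to 20 without 1 library (20 without male control replicate 1) and 7 with voom weights, alone or with equal totals. Those on PLX3397 (1064) were 332 to 1242 without 1 library (332 and 469 without male PLX3397 replicate 2 or 3, and 677, 480 and 709 without female PLX3397 replicate 2, 3 or 4). They were 669 without a filter, 606 with upper-quartile scaling, 467 with quantile normalisation, 44 fitted to their groups alone, 571 with equal totals, 468 with voom and equal totals, and 345 without the doubted pair. The overlap of male and female calls (746) was 584 to 766 without 1 library and up to 851 in all, with equal totals.

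Lists called with an estimated correlation were 0 in males, 1 in females, 0 for the difference in response, 2 between the sexes on control chow and 0 on PLX3397, against 15, 18, 10, 5 and 19. By exact permutation of the mean per library 0 passed in each, which says nothing against the lists where 4 libraries were set against 4. There 21 of 35 lists would have to reach the smallest p of 0.0286 for any to pass, and 17 did in males, 16 in females, 2 between the sexes on control chow and 11 on PLX3397. The difference in response had 4900 relabellings and was not held to that limit. For it 3 lists had an unadjusted exact permutation p under 0.05 and 0 passed, so this test gave the 10 camera calls no support. Fry called 0 for the difference and 2 on control chow, where quantile normalisation and voom with equal totals called 3 each. Without 1 library 2 to 15 were called there (2 without female control replicate 1, 15 without female control replicate 2, 3 without male or female control replicate 3), 13 to 17 in males, 17 to 21 in females, 8 to 13 for the difference and 17 to 20 on PLX3397. Quantile normalisation called 11 on PLX3397. With quantile normalisation camera's direction reversed for phagocytosis and complement in males (median -0.021583), for the lysosome in the difference (-0.044126) and on PLX3397 (-0.053491), and for disease-associated genes on PLX3397 (-0.25862). Ribosomal proteins on control chow reversed to 0.067909 without female control replicate 2, and had -0.053404 without female control replicate 3. Replicate numbers do not pair the libraries (median correlation of pairs with the same number 0.00484, -0.0446 to 0.115), and with a replicate block the counts were 2136, 962, 0, 12 and 863 in the order of the comparisons. In the simulated male comparison, 2-fold changes were recovered for 28 of 31 genes with a mean over 500 and 2 of 32 with a lower mean.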

Other observations

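The tests below were chosen before the results were seen, and which of the fixed lists to describe here was chosen after. On gene groups not yet described, glycolytic genes moved in females on PLX3397: 6 of 25 rose, 1 fell and 18 did not pass, with 11 higher and 3 lower when adjusted over the list alone (median 0.39, camera adjusted p = 0.00183; adjusted p = 0.305 with an estimated correlation). In males the list did not pass (camera adjusted p = 0.365), and the difference between the responses was not among the 10 lists called. Immediate early and dissociation stress genes rose in 5 of 27 cases in females and 22 did not pass, with 9 higher and 1 lower when adjusted over the list alone (median 0.57, camera adjusted p = 0.000988; adjusted p = 0.133 with an estimated correlation). Lipid efflux and storage genes rose in 5 of 19 cases and 14 did not pass, with 5 higher when adjusted over the list alone (median 0.10, camera adjusted p = 0.00951; adjusted p = 0.239 with an estimated correlation); of these 19 genes, 4 are also on the disease-associated list.

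Cytosolic chaperones were higher in females than in males on PLX3397, with 5 of 30 genes higher and 25 not past the test, and 9 higher when adjusted over the list alone (median 0.39, camera adjusted p = 2.82e-06; adjusted p = 0.336 with an estimated correlation). Sterol synthesis genes were higher there in 2 of 19 cases, with 5 when adjusted over the list alone (median 0.31, camera adjusted p = 0.00458; adjusted p = 0.204 with an estimated correlation). The disease-associated and lysosome lists share 5 genes, and the disease-associated and phagocytosis lists 3, so their calls are not independent.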
